A study of Rattus norvegicus with 4 samples.

How the data were processed

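Total RNA from liver and skeletal muscle of Sprague-Dawley rats, an outbred laboratory strain, was profiled on Illumina bead arrays, on which each probe is read from many beads of its kind. Per the labels, the animals were 8 weeks old, and the model group of type 2 diabetes had received an intraperitoneal injection of streptozotocin, a toxin of the insulin-producing beta cells, at 30 mg/kg. The labels give 4 arrays in all, 1 for each combination of tissue and condition: liver control, liver diabetes, muscle control and muscle diabetes. Per the labels' protocols, RNA was purified with Trizol and an RNeasy column with DNase I, and biotinylated cRNA was made with an Ambion MessageAmp kit. Whether the RNA of an array came from a single rat or from several, and whether liver and muscle came from the same rats, is not given in the sources used here. Nor are the muscle that was sampled, the fasting state, the time of sampling or the scanner software.

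The authors deposited a non-normalized table of average bead intensities on a linear scale, without background subtraction or scaling between arrays, with 22517 probe rows. Beside each intensity stands a detection p-value, per the file headers, which took steps of 1 in 825 and therefore compares a probe with that many negative control values. The deposited processed table holds intensities that are again linear and not scaled between arrays. Each of its 22226 rows equalled the same row of the non-normalized table, within 0.1 units, after subtraction of a constant of 75.0 for liver control, 73.5 for liver diabetes, 71.0 for muscle diabetes and 72.8 for muscle control. The medians of the processed intensities were 7.6, 10.6, 8.7 and 9.8 in that order.

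The probe identifiers of both tables agreed up to a point and differed from row 252 on. All 22226 identifiers of the processed table were, in order, the distinct identifiers of the non-normalized table, while its values followed every row of that table, repeated identifiers included, and stopped 291 rows before its end. With the identifiers of the non-normalized table, 12 of 14 hepatocyte marker genes were over 1000 units brighter in the liver control array than in the muscle control array, against 0 with those of the processed table. For skeletal muscle fibre markers, 13 of 13 were over 1000 units brighter in the muscle control array, against 2. The identifiers of the non-normalized table were therefore used throughout, and the processed values entered as an alternative, matched by row.

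Probe identifiers were named through the platform annotation, in which 13192 had 1 gene symbol, 0 had several and 9034 were not listed. Symbols were updated through gene identifiers in the RefSeq table of assembly GRCr8, which held 13088 of them and was used for names alone. The 571 rows whose identifier occurred more than once (280 identifiers) were left unnamed, which left 13129 named rows and 12925 genes. Where a gene had more than 1 probe (201 genes), the probe with the highest mean over the 4 arrays represented it. Members of the cytochrome P450 families Cyp2, Cyp3a and Cyp4a, of the Mup and RT1 families and of the globins share sequence with close relatives, so probes of these genes can bind the RNA of a relative, and their values are uncertain.

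Background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3, with the mean and spread of the negative controls inferred from the detection p-values, an offset of 16 and quantile normalization over the 4 arrays. Values are log2, and each difference is diabetes minus control within a tissue. A probe counted as detected on an array at a detection p-value under 0.01. Genes detected on at least 1 array of a tissue were compared there. For a gene detected on 1 array only, the undetected side was set to the higher of its own value and the lowest detected value of that array, so the difference is a bound, written as at least a given fold. Where the undetected side then still lay above the detected one, the difference was set to 0. Genes at least 2-fold apart, which is a log2 difference of 1 or more in size, were counted. The tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

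With 1 array per group there were no replicates, so no test, p-value or standard error was computed and no difference has a replicate check. The number of arrays limits the precision. As a yardstick within arrays, differences measured by separate detected probes of the same gene had a pooled standard deviation of 0.22 in liver (41 genes) and 0.22 in muscle (33 genes), which leaves out all variation between animals, extractions and hybridisations.

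Before the data were examined, 31 gene lists (metabolic pathways, hormone responses, stress and inflammation, fibre types and cell division) and 13 lists of cell type markers were written. A list is described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these arrays. A list is said to stand apart when the percentile lies below 2.5 or above 97.5, and lists with fewer than 5 measured members have no percentile. Named genes followed a rule written along with the lists: in each tissue the 8 largest differences in each direction among genes detected on both arrays, the 3 largest bounds in each direction, up to 4 members of each list with the largest differences in size, and up to 5 genes 2-fold apart in the same and in opposite directions in both tissues. Predicted genes and clone names were passed over. List entries were matched to genes by current symbol, and by an older name only where the entry is no gene's current symbol and the older name belongs to 1 gene. This last condition was added after the first list results had been seen, because older names had matched some entries to unrelated genes.

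The procedure was tested on simulated arrays with known differences, which differed in brightness as the real arrays did. Their noise was the spread of 0.22 between probes of a gene, beside background noise. Variation between animals, extractions and hybridisations was left out, and changed genes were drawn only from probes above background. The rates below therefore say nothing about false calls between animals or about dim genes. In the simulated liver comparison over 6260 genes, 97 of 100 genes with a true log2 difference of 2 in size and 83 of 100 with one of 1.33 were called at least 2-fold apart in the right direction, and 1 of 6060 unchanged genes was called. In the simulated muscle comparison over 6024 genes the numbers were 98 of 100, 78 of 100 and 2 of 5824. Of 40 random unchanged lists, 2 stood apart in the simulated liver comparison and 0 in the muscle one. The simulated noise was independent between genes, so this says nothing about lists of genes that vary together.

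Alternatives fixed along with the lists were quantile normalization within each tissue, scaling to a common median, the authors' processed values, no background correction, an offset of 50, a detection p-value under 0.05, detection on both arrays, no detection filter, the mean over a gene's detected probes and a 1.5-fold threshold.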

Results

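The study compared gene expression in liver and skeletal muscle of rats with streptozotocin-induced type 2 diabetes and of control rats. Each of the 4 groups was represented by 1 array and there were no replicates, so every value below describes these arrays. The mean intensity was 362 units on the liver control array, 466 on the liver diabetes array, 493 on the muscle control array and 409 on the muscle diabetes array. The numbers of probes detected were 8237, 8562, 8080 and 7681 in that order. Brightness thus differed with condition, upward in liver and downward in muscle, before normalization.

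The arrays carried the tissues named in their labels. Hepatocyte markers had a median intensity of 29237 units on the liver control array and 32683 on the liver diabetes array, against 75.4 and 86.2 on the muscle control and muscle diabetes arrays. Skeletal muscle fibre markers had a median of 30095 units on the muscle control array and 27357 on the muscle diabetes array, against 79.6 and 82.8 on the liver control and liver diabetes arrays. In muscle the brightest hepatocyte marker reached 107 units, and in liver the brightest muscle marker reached 139.

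In liver, the comparison asked which transcripts differed between diabetes and control. The diabetes array was higher in a broad set of fast-responding and glucocorticoid-responsive genes, in genes of glucose production and in interferon-induced genes. It was lower in the acute phase genes Lcn2 and A2m, in globins and in heat shock genes. Among genes with a name, the largest higher values were those of Insig1, a brake on cholesterol synthesis, and Noct, a clock-regulated gene of metabolism, each 18.8-fold higher (4.23 on the log2 scale). Lcn2, which encodes an iron-binding protein of inflammation, was the lowest, at -4.75, with an intensity of 7046 units on the control and 417 on the diabetes array.

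Of 6345 genes compared in liver, 162 were at least 2-fold higher and 79 at least 2-fold lower in diabetes, among them 17 and 7 bounds. At 4-fold the numbers were 31 and 3. The next largest higher values were 3.77 for Zfp354a, a zinc finger gene of kidney and liver, 3.65 for Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, 3.36 for Myc, 3.26 for Egr1, 2.73 for Per1 and 2.71 for Slc38a2, an amino acid transporter. The lowest values after Lcn2 were -2.67 for the protease inhibitor A2m, -1.94 for Osgin1, -1.92 for the acyl-CoA thioesterase Acot3, -1.86 for the hepatokine Fgf21, -1.83 for Akr1c2, -1.82 for the transporter Abcg2 and -1.78 for Mrpl18. Among genes detected on the diabetes array only, Chac1 was at least 6.17-fold, Cxcl10 at least 4.91-fold and Atf3 at least 3.98-fold higher. Among genes detected on the control array only, Pbsn was at least 4.87-fold, Pcdh18 at least 2.84-fold and Cxcr4 at least 2.73-fold lower.

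**Figure D1:**
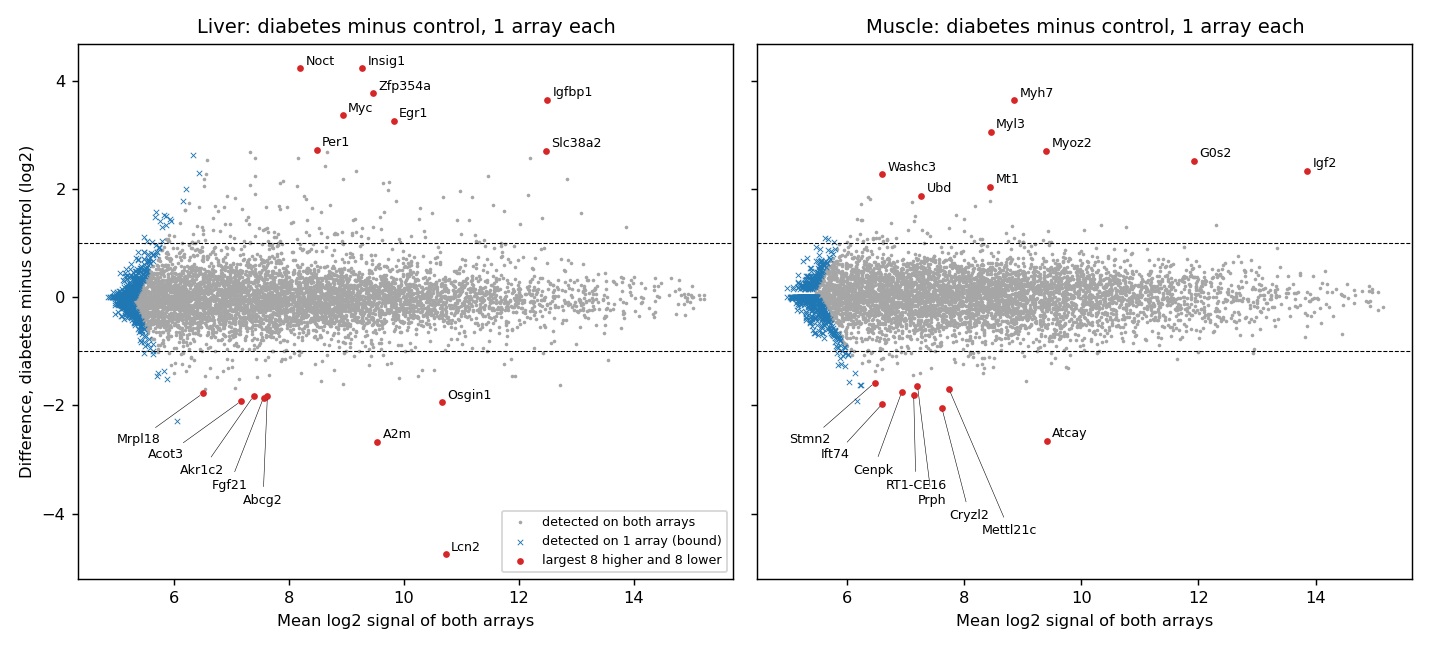
Difference between the diabetes and the control array (log2, vertical axis) against the mean log2 signal of both arrays (horizontal axis) for each gene compared in liver (left) and muscle (right), with 1 array per group. Dashed lines mark 2-fold, crosses are bounds for genes detected on 1 array, and the labelled points are the 8 largest values in each direction, from 4.23 for Insig1 to -4.75 for Lcn2 in liver and from 3.64 for Myh7 to -2.65 for Atcay in muscle.

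The immediate early list, genes induced within minutes of a stimulus, had the highest median of any list in liver, 1.42 (percentile 100), with 11 of 18 measured members at least 2-fold higher and 0 lower. Beside Myc and Egr1, Jun was at 2.58 and Gadd45b at 2.57. The glucocorticoid response list had a median of 1.17 (percentile 100), with 8 of 14 members at least 2-fold higher, led by Igfbp1, Per1 and Tat, the enzyme of tyrosine breakdown, at 2.19. Its 1 member past 2-fold in the other direction was Lcn2. The gluconeogenesis list had a median of 0.48 (percentile 99.99), and 6 of 14 members were at least 2-fold higher. Among these were G6pc1, the glucose-6-phosphatase that releases glucose from the hepatocyte, at 2.58, the kinase Sik1 at 2.13, Sds, which degrades serine, at 1.56, and the aminotransferase Got1 at 1.47. The enzymes of glycolysis had a median of -0.048, inside the random range (percentile 39.98), although Ldha was at -1.14.

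Interferon and antigen presentation genes had a median of 0.47 (percentile 100) in liver, with 6 of 17 members at least 2-fold higher. Mx1 was at 2.53, Irf7 at 2.25, Mx2 at 2.18 and Gbp2 at 2.10. Macrophage markers moved with them, with a median of 0.49 (percentile 100), 9 of 11 members above 0, Marco at 1.45 and Aif1 at 1.15. Lymphocyte markers were lower, with a median of -0.46 (percentile 1.15) over 5 members and Cd79b at -0.63, a bound, and stood apart under 6 of 8 alternatives. Both measured neutrophil markers, Lcn2 and S100a8 (-1.37), were at least 2-fold lower, with a median of -3.06. The acute phase list as a whole was inside the random range, with a median of -0.054 (percentile 28.84), 4 of 32 members at least 2-fold lower and 2 higher, Cxcl10 and Nfkbia at 1.44, but it stood apart as low with median scaling and with the authors' processed values (percentile 0.00 in each). Its members Fgb, Fgg and Hpx lay near the brightest probes, where a rise could be hidden, so these low percentiles decide nothing. Fgg had 39171 units on the control and 41107 on the diabetes array, whose brightest probes had 39171 and 41398. Erythroid markers were lower without reaching 2-fold, with a median of -0.76 (percentile 0.00) over 5 members, Hbb-b1 at -0.94 and Hbb at -0.87, and the globin probes are uncertain.

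Growth-hormone-patterned liver genes had a median of 0.28 (percentile 99.96), with Socs2, a feedback inhibitor of cytokine signalling, at 2.07 and Onecut1 at 1.44 as the members past 2-fold. The insulin signalling list had a median of 0.13 (percentile 97.91), with 3 of 28 members at least 2-fold higher: Igfbp1, Irs1 at least 2.64-fold and Trib3 at 1.18. This list stood apart under only 3 of 9 alternatives, with a percentile down to 78.2. The muscle atrophy and autophagy list stood apart in liver at a median of 0.20 (percentile 99.31), with 12 of 19 members above 0, among them Ddit4 at 1.47, Klf15 at 1.11 and Bnip3 at 1.02, genes that answer to glucocorticoids or low oxygen, and did so under 8 of 9 alternatives. Drug metabolism genes had a median of 0.12 (percentile 98.89), with 1 of 40 members, Gsta3 at 1.69, past 2-fold, and stood apart under 7 of 9 alternatives. On the lower side stood heat shock genes, with a median of -0.31 (percentile 1.06), Hsp90aa1 at -1.08 and Chordc1 at -1.06. Oxidative phosphorylation genes had a median of -0.11 (percentile 1.65), with 0 of 57 members past 2-fold. With median scaling the median was 0.18, against 0.23 for all genes, and the list still stood apart as low (percentile 2.29). With the authors' processed values the median was 0.41, against 0.49 for all genes, and the list no longer stood apart (percentile 6.47).

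Lists of lipid genes in liver lay inside the random range in the main setting. Fatty acid oxidation genes had a median of -0.013 (percentile 53.57), with Pdk4, which blocks pyruvate oxidation, at 2.68 and the lipoprotein lipase inhibitor Angptl4 at 1.18 against Acot3 and Fgf21. Fatty acid synthesis genes had a median of -0.13 (percentile 15.46), with Thrsp at -0.82 and 0 of 14 members past 2-fold, and stood apart with median scaling (percentile 2.15). The list of lipid uptake and storage had a median of -0.070 (percentile 33.09), with G0s2, an inhibitor of the lipase Pnpla2, at -1.45. Cholesterol synthesis genes had a median of 0.11 (percentile 87.66), with Insig1 and Stard4 (1.24) past 2-fold. Bile acid genes had a median of 0.17 (percentile 96.58), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 1.35, Nr0b2 at 1.12 and Cyp7b1 at 1.07. The list stood apart with quantile normalization within each tissue, without background correction and without the detection filter. Amino acid breakdown genes had a median of 0.11 (percentile 97.17), with 4 of 31 members at least 2-fold higher, among them Tat and Aass (1.65), and stayed inside the random range under only 4 of 9 alternatives. In the unfolded protein response list (median 0.021, percentile 71.11), 4 of 21 members were at least 2-fold higher, including Chac1, Atf3 and Ppp1r15a (1.87).

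The remaining lists in liver lay inside the random range, except that hepatocyte markers and cell division genes stood apart as low with median scaling and with the authors' processed values. Their medians were 0.00 for hepatocyte markers, 0.032 for adipocyte, 0.057 for endothelial, 0.069 for fibroblast and matrix, and -0.10 for cholangiocyte markers. Many hepatocyte markers lay near the brightest probes, where a difference could be hidden. Fgb had 32404 units on the control and 35658 on the diabetes array but the same normalized value. The median and low percentiles of hepatocyte markers therefore do not show whether these genes differed. Ccn2 was at 2.18 among the fibroblast and matrix genes. Medians were -0.13 for glycogen metabolism, 0.065 for the citrate cycle, 0.013 for mitochondrial biogenesis, -0.079 for ribosomal proteins and -0.042 for the proteasome. They were -0.092 for antioxidant genes, 0.16 for myogenic genes, -0.15 for the circadian clock and -0.19 for cell division. Members of these lists past 2-fold included Rpl30 at 2.43, Psmd5 at -1.47, Sod3 at 1.42, Csnk1d at 1.25 and Ccnd1 at -1.46. Lists with too few measured members for a percentile had medians of 0.22 for ketone body metabolism (4 members), 0.20 for smooth muscle (3), 1.20 for pancreas acinar cells (2, Cpb1 and Cela1), -0.040 for nerve and Schwann cells (3), -0.38 for slow fibre (4) and -0.43 for fast fibre genes (4). Skeletal muscle fibre markers, with 2 measured, had a median of 2.1e-05.

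The liver counts depended on the processing. With arrays scaled to a common median, 293 genes were at least 2-fold higher and 35 lower, and 89.3% of these calls were higher against 67.2% in the main setting, while with the authors' processed values, which are not scaled, the counts were 780 and 27 (96.7% higher). Without background correction they were 98 and 34, and with an offset of 50 the number lower was 43.

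**Figure D2:**
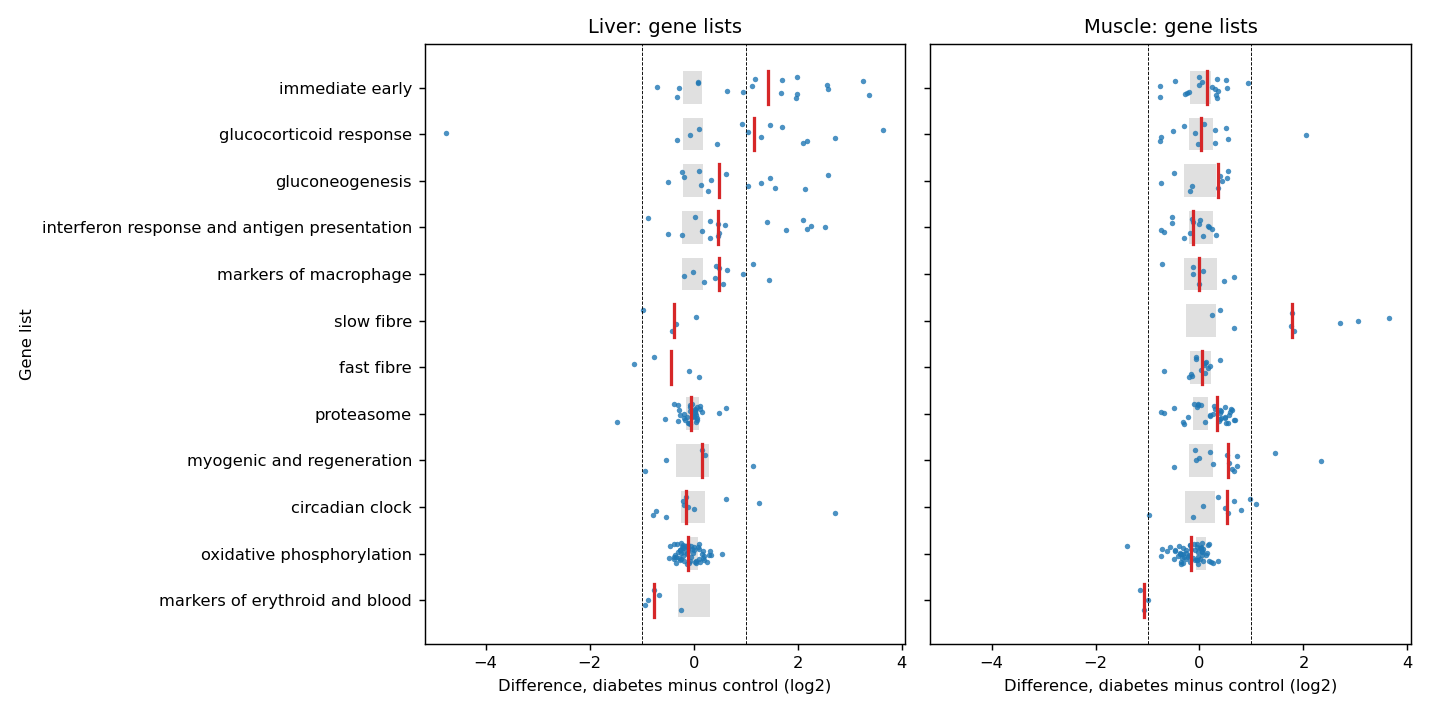
Differences between the diabetes and the control array (log2, horizontal axis) for the measured members of 12 gene lists (vertical axis) in liver (left) and muscle (right), 1 point per gene, with the list median in red and, where a list has at least 5 members, the central range of medians of matched random lists in grey. The immediate early list has its median at 1.42 in liver and 0.14 in muscle, and the slow fibre list at 1.77 in muscle, and dashed lines mark 2-fold.

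In muscle, the same question was asked of the muscle arrays. The diabetes array was higher in slow-twitch contractile genes, in the growth factor Igf2, in the lipase inhibitor G0s2 and in the metallothionein Mt1. It was lower in the neuronal genes Atcay, Npy and Dbh, in the 3 globins measured and in the matrix genes Col1a1 and Postn. Myh7, the heavy chain of slow myosin, was 12.5-fold higher (3.64 on the log2 scale), with an intensity of 201 units on the control and 1620 on the diabetes array. Atcay, a gene of neurons, was the lowest, at -2.65.

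Of 5903 genes compared in muscle, 68 were at least 2-fold higher and 76 at least 2-fold lower in diabetes, among them 3 and 15 bounds. At 4-fold the numbers were 7 and 2. After Myh7, the largest higher values were 3.06 for the slow myosin light chain Myl3, 2.70 for Myoz2, a Z-disc protein of slow fibres, 2.52 for G0s2, 2.34 for Igf2, 2.27 for Washc3, 2.05 for Mt1 and 1.88 for the ubiquitin-like Ubd. The lowest values after Atcay were -2.05 for Cryzl2, -1.97 for Ift74, -1.80 for RT1-CE16, -1.75 for Cenpk, -1.70 for Mettl21c, a muscle methyltransferase, -1.63 for the neuronal intermediate filament Prph and -1.58 for Stmn2, a gene of growing axons. The value of RT1-CE16 is uncertain because class I genes resemble each other. Among genes detected on the control array only, the neuropeptide gene Npy was at least 3.77-fold, Smc4 at least 3.09-fold and Dbh, the enzyme that makes noradrenaline, at least 3.06-fold lower. Among genes detected on the diabetes array only, Trim16 was at least 2.15-fold, Sqor at least 2.12-fold and Serpina3n at least 2.04-fold higher.

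The slow fibre list had the highest median of any list in muscle, 1.77 (percentile 100), with 9 of 9 measured members above 0 and 6 at least 2-fold higher, among them the slow troponin Tnnt1 at 1.81. The fast fibre list had a median of 0.057 (percentile 63.55) over 14 members, 0 of them past 2-fold, with Pvalb at -0.68, Ldha at 0.40, Myl11 at 0.21 and Tnnt3 at -0.19. General muscle fibre markers had a median of -0.064 (percentile 20.26). Ldhb, the lactate dehydrogenase of oxidative tissue, was at 1.52 in the glycolysis list, whose median was 0.12 (percentile 81.92). Oxidative phosphorylation genes were lower, with a median of -0.16 (percentile 0.02) over 59 members, Atp5mk at -1.40 and Ndufb3 at -0.75. Myogenic and regeneration genes had a median of 0.55 (percentile 100), with Igf2 and the cell cycle inhibitor Cdkn1a (1.45) past 2-fold, Chrnd at 0.73 and embryonic Myh3 at 0.72.

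Proteasome genes were higher than the genes around them in muscle, with a median of 0.34 (percentile 100) and 24 of 34 members above 0. With the unscaled processed values of the authors the median was -0.017. All genes in muscle had a median of -0.24 in that setting, and the list stayed at percentile 100. 0 members reached 2-fold: Psmd3 was at 0.68 and Psmd2 at 0.67, whereas the immunoproteasome subunits Psmb8 and Psmb9 were at -0.74 and -0.69. The muscle atrophy and autophagy list had a median of 0.19 (percentile 97.57), with Mt1, Cdkn1a and Fbxo32, the ubiquitin ligase atrogin-1, at 1.19 past 2-fold, and the median was -0.072 with median scaling and -0.18 with the processed values; it stood apart in the same direction under 5 of 9 alternatives. Circadian clock genes had a median of 0.52 (percentile 100) over 10 members, with Csnk1d at 1.09, Bmal1 at 0.97 and Nr1d1 at 0.80 against Per2 at -0.97. Antioxidant and metallothionein genes had a median of 0.16 (percentile 95.02), with Mt1, Gpx3 at 1.30 and Gsr at 1.04 past 2-fold.

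Fatty acid synthesis genes had a median of 0.46 (percentile 99.93) in muscle, with Thrsp at 1.02, Nr1h3 at 0.84 and Srebf1 at 0.71. Lipid uptake and storage genes had a median of 0.25 (percentile 97.61), led by G0s2, and the median was -0.014 with median scaling and -0.033 with the processed values. Gluconeogenesis genes had a median of 0.35 (percentile 98.31) but 0 of 9 members past 2-fold and Pck1 at -0.75, and the median was -0.053 at a detection p-value under 0.05 and -0.14 without the filter. Amino acid breakdown genes had a median of 0.35 (percentile 99.53), with Bckdha at 0.73 and Bcat2 at 0.67, both enzymes of branched-chain amino acids. Insulin signalling genes had a median of 0.26 (percentile 99.41), with Igfbp3 at -0.97, Rps6kb1 at -0.82 and Akt2 at 0.62. The median was -0.024 without the detection filter (percentile 24.3). With the processed values, which shifted all genes, it was -0.0054, but the list still stood apart as high (percentile 98.59). Drug metabolism genes had a median of 0.33 (percentile 99.76), with the glutathione transferases Gstm2 at 1.24 and Gstt2 at 1.04 past 2-fold. Growth-hormone-patterned genes had a median of 0.39 (percentile 99.26), with Cish at 1.44 and Mup5, an uncertain family member, at 1.07. Hepatocyte markers were near background in muscle, but 4 of 14 (Hpx, Cyp2e1, Ahsg and Serpina1) were detected on the diabetes muscle array against 1 on the control array, and their list stood apart at a median of 0.55 with a detection p-value under 0.05 and 0.35 without the filter. Bile acid genes, with 5 measured, had a median of -0.45 (percentile 2.23), with Cyp7b1 at -1.25 and Abcb4 at -1.18, but stood apart under only 1 of 8 alternatives, and the median was 0.032 without the filter. With a median of the same sign, the lists of lipid uptake, gluconeogenesis and amino acid breakdown each stood apart under 5 of 9 alternatives, insulin signalling under 6, growth-hormone-patterned genes under 7, and fatty acid synthesis and drug metabolism under 8.

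Fibroblast and matrix markers had a median of -0.24 (percentile 1.75) in muscle, with Col1a1 at -1.37 and Postn at -1.12, while Sparc was at 0.86, and stood apart under 7 of 9 alternatives. Lymphocyte markers had a median of -0.42 (percentile 0.18) over 5 members, all bounds, with Prf1 at -0.62. As bounds from detection on the control array only, their differences could not lie above 0, and the random lists were not matched on this. The percentile is therefore weak here, although the list also stood apart without the detection filter, where no bounds are set. The 3 globins measured were lower, with a median of -1.06, Hba-a1 at -1.14, Hbb-b1 at -1.06 and Hbb at -0.98, and their probes are uncertain. Macrophage markers had a median of -0.018 (percentile 33.83), endothelial markers -0.048 (30.67), adipocyte markers -0.16 (14.35) and hepatocyte markers 0.19 (87.63). The nerve and Schwann cell list, with 4 measured, had a median of 0.26, with Nefl at least 1.53-fold lower, Cnp at 0.66 and Pmp22 at 0.28. Medians were 0.32 for smooth muscle (3 measured), -0.039 for neutrophil (2) and 0.23 for pancreas acinar markers (1), and 0 cholangiocyte markers were measured.

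The other lists in muscle lay inside the random range, except that immediate early genes stood apart with median scaling and with detection on both arrays, and unfolded protein response genes without the detection filter. Medians in the main setting were 0.074 for glycogen metabolism, 0.049 for fatty acid oxidation, 0.16 for cholesterol synthesis, 0.13 for acute phase and -0.12 for interferon genes. They were 0.094 for the citrate cycle, -0.0016 for mitochondrial biogenesis, -0.032 for ribosomal proteins, 0.16 for the unfolded protein response and 0.16 for heat shock. Immediate early genes had a median of 0.14, glucocorticoid response genes 0.027 and cell division genes 0.072, and ketone body genes, with 3 measured, 0.13. Members of these lists past 2-fold included Gbe1 at 1.05, Pdk4 at -1.08, Ccl5 at -1.30, Rps16 at -1.24, Chac1 at 1.19 and Hspb7 at 1.23.

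The muscle counts also depended on the processing. With median scaling, 32 genes were at least 2-fold higher and 207 lower (13.4% higher against 47.2% in the main setting), and with the authors' processed values the counts were 58 and 346 (14.4% higher). Without background correction they were 25 and 23, and with an offset of 50 they were 33 and 36.

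The differences of both tissues were then set against each other to ask whether liver and muscle differed alike. Across 4617 genes detected on all 4 arrays, Pearson's r was -0.014 and Spearman's rho was -0.029, and 48.5% of genes had the same sign; this is across genes, which are not independent replicates. Of 5168 genes measured in both tissues, 5 were at least 2-fold higher in both against 1.10 for independent lists, and 4 were at least 2-fold lower in both against 0.66. Those named by the rule were Chac1 (at least 6.17-fold in liver and 1.19 on the log2 scale in muscle), Igf2 (1.14 and 2.34), RT1-CE16 (-1.04 and -1.80), Col1a1 (at least 2.06-fold lower in liver and -1.37 in muscle) and Pmepa1, a target of transforming growth factor beta (1.13 and 1.23). A further 4 were higher in liver and lower in muscle against 1.39 for independent lists, and 2 were the reverse against 0.53. G0s2 was at -1.45 in liver and 2.52 in muscle, Pdk4 at 2.68 and -1.08, Slfn4 at 2.34 and -1.09, Hmgn1 at 1.14 and -1.56, and Ammecr1l at -1.18 and 1.17. These counts depended on the processing. The 9 genes in the same direction became 2 with median scaling, 1 without background correction, 3 with an offset of 50 and 18 with the authors' processed values, and the 6 in opposite directions became 13, 2, 3 and 47. Of the genes named, RT1-CE16 in liver stayed past 2-fold under 4 of 9 alternatives and Col1a1 in liver under 5 of 8.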

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

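All tests of explanations in this part were chosen after the results were seen.

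The 6 genes at least 2-fold apart in opposite directions in the tissues differed between the tissues in that the single comparison of each tissue went the other way, and the difference was not tested. G0s2 was at -1.45 in liver and 2.52 in muscle, Pdk4 at 2.68 and -1.08, Slfn4 at 2.34 and -1.09, Hmgn1 at 1.14 and -1.56, Ammecr1l at -1.18 and 1.17, and Cyp7b1 at 1.07 and -1.25. Among probes without a gene name, which the comparisons of genes did not use, 49 of 2528 detected in liver were at least 2-fold higher on the diabetes array and 34 lower, with values from -2.95 to 4.46, the highest above that of any named gene. In muscle 18 of 2363 were higher and 65 lower.

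In liver, immediate early and glucocorticoid response genes were higher together on the diabetes array, with medians of 1.42 and 1.17. A common scaling shift as the whole cause is argued against: the lowest median of either list over the alternatives was 0.97, while the median of all genes in liver reached 0.49 at most, with the authors' processed values. A stress or glucocorticoid response of the whole animal at sampling is a candidate explanation that stays open: the same glucocorticoid list in muscle lay at percentile 52.9, but its members went both ways there, and the labels do not say whether both tissues came from the same rats. Diabetes itself stays open and untested, since condition, animal and array cannot be told apart with 1 array per group. Fasting state and time of sampling are not given, so a difference in either cannot be told apart from it.

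In muscle, slow fibre genes were higher with a median of 1.77 while fast fibre genes had a median of 0.057. These medians are not a like comparison, since some fast fibre genes lay near the brightest probes, where a rise could be hidden. Tnnc2 had 38200 units on the control and 32909 on the diabetes array, whose brightest probes had 38200 and 35407. Myh7 had 201 units on the control array. A common scaling shift as the whole cause is argued against: the lowest median of the slow fibre list over the alternatives was 1.22, while the median of all genes in muscle was no farther from 0 than -0.24. A sample with a larger share of slow fibres, taken from another site, may account for it, and would be expected to raise oxidative phosphorylation genes, whose median was -0.16. Those genes have a high baseline in all fibres, so a small added share would not show, and a difference of dissection and a change of fibre type with diabetes cannot be told apart here.

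Npy, Dbh, Prph and Stmn2, genes of sympathetic neurons, were lower on the diabetes muscle array and prompted a longer list, whose other 15 measured members had a median of -0.38 in muscle, with 10 below 0 and 4 at least 2-fold lower (Gap43, Slc6a2, Syt1 and Cyb561), but 0 without background correction. Of these 15, 5 were detected on both muscle arrays, of which 3 were below 0 and 0 were 2-fold lower. Of the 19 measured with the prompting genes, 2 are also on the nerve and Schwann list and 7 were detected on both muscle arrays. A further 11, among them Gap43, Slc6a2, Syt1 and Cyb561, were detected on the control array only. As bounds, the differences of such genes could not lie above 0. In liver the list had 0 of 9 members above 0 and a median of -0.22 (percentile 5.15). With the authors' processed values its median was 0.10 (percentile 5.01), where all genes in liver had a median of 0.49. With median scaling it was -0.12 (percentile 1.67). Neuronal cell bodies in the control sample, as in a sympathetic ganglion, are a candidate source that stays open: Th, Dbh, Slc6a2 and Npy, 4 genes, were detected on the control muscle array (126, 211, 177 and 246 units) and not on the diabetes array, which decides nothing, since Dbh and Npy prompted the explanation. Peripheral nerve with its Schwann cells may be another, although the lower of the differences of Pmp22 and Cnp was 0.28, and these genes are expressed by other cells too. These sources and an effect of diabetes on nerves cannot be told apart with 1 array per group.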

How the results depend on the processing

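All alternatives here were planned, and the cause of a change was not tested unless stated. Of 123 named genes at least 2-fold apart, 72 stayed past 2-fold under every alternative that measured them. Of 29 lists that stood apart, 13 did so with a median of the same sign under all alternatives that gave a percentile: erythroid and macrophage markers, gluconeogenesis, growth-hormone-patterned, interferon, heat shock, immediate early and glucocorticoid response genes in liver, and lymphocyte markers, oxidative phosphorylation, slow fibre, myogenic and circadian clock genes in muscle. Muscle proteasome genes also stood apart as high under all 9 alternatives (lowest percentile 99.99), but their median was -0.017 with the processed values. Over the alternatives the median ranged from 1.01 to 2.22 for immediate early and from 0.97 to 1.70 for glucocorticoid response genes in liver, and from 1.22 to 1.86 for slow fibre genes in muscle. Signal over background limits which genes have a value: 220 liver genes were detected on the control array only and 453 on the diabetes array only, and in muscle 396 and 153. The main counts were 162 higher and 79 lower in liver, 68 and 76 in muscle, 9 in the same and 6 in opposite directions, and the correlation was -0.014.

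Median scaling moved the median of all genes to 0.23 in liver and -0.19 in muscle, and the authors' processed values moved it to 0.49 and -0.24, so list medians under these scalings are read by their percentile among genes shifted alike. Genes near the brightest probes may not shift alike. Median scaling gave 293 and 35 genes in liver, 32 and 207 in muscle, 2 in the same and 13 in opposite directions, and a correlation of -0.037. The authors' processed values gave 780 and 27 in liver, 346 lower in muscle, 18 in the same and 47 in opposite directions, and a correlation of -0.020. No background correction gave 98 and 34, 25 and 23, 1 and 2. An offset of 50, which shrinks differences of dim probes, gave 43 lower in liver, 33 and 36 in muscle, 3 and 3. The 1.5-fold threshold, which admits more genes by construction, gave 451 and 378, 378 and 411, 65 and 55. Without the detection filter the correlation was 0.015.

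Among the 29 lists that stood apart, medians that changed sign were, with median scaling, liver oxidative phosphorylation (0.18), muscle lipid storage (-0.014) and muscle atrophy genes (-0.072). With the processed values they were liver oxidative phosphorylation (0.41), muscle lipid storage (-0.033), insulin signalling (-0.0054), proteasome (-0.017) and atrophy genes (-0.18). Without the detection filter they were muscle gluconeogenesis (-0.14), bile acid (0.032) and insulin signalling genes (-0.024), and at a detection p-value under 0.05 muscle gluconeogenesis (-0.053). Except for liver oxidative phosphorylation with median scaling, and muscle insulin signalling and proteasome genes with the processed values, these lists also no longer stood apart. Of the 44 other lists that had a percentile, 22 had a median of another sign with median scaling and 25 with the processed values. Those scalings shifted all genes, so a list median near 0 could change sign with them. The numbers were 4 at a detection p-value under 0.05, 7 without the filter, 1 with detection on both arrays and 1 with the mean over probes.

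Further lists, whose medians kept their sign, no longer stood apart: with median scaling, liver lymphocyte markers (-0.19), drug metabolism (0.38) and insulin signalling (0.35), and muscle gluconeogenesis (0.038) and bile acid genes (-0.60). With the processed values they were liver lymphocyte markers (-0.0051), drug metabolism (0.57) and insulin signalling (0.67), and muscle gluconeogenesis (0.018). With quantile normalization within tissues they were muscle lipid storage (0.25) and bile acid genes (-0.45), and with the mean over probes muscle bile acid genes (-0.45). Without background correction they were liver insulin signalling (0.075), muscle bile acid (-0.21) and amino acid genes (0.17), and with an offset of 50 muscle bile acid (-0.27) and amino acid genes (0.21). With detection on both arrays they were liver insulin signalling (0.064) and muscle lipid storage (0.21). Without the detection filter they were liver insulin signalling (0.030) and atrophy genes (0.095), and muscle matrix markers (-0.19), fatty acid synthesis (0.17), growth-hormone-patterned (0.072), amino acid (0.054) and atrophy genes (0.13). At a detection p-value under 0.05 they were liver insulin signalling (0.092), and muscle matrix markers (-0.21), bile acid (-0.027), drug metabolism (0.14), growth-hormone-patterned (0.17), insulin signalling (0.18), amino acid (0.11) and atrophy genes (0.19). Detection on both arrays left too few lymphocyte markers in either tissue, and too few muscle bile acid genes, for a value, and of the 44 other lists 39 had one.

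Lists that newly stood apart, some with another sign because all genes shifted, were, with median scaling, liver hepatocyte markers (-0.058), fatty acid synthesis (0.090), amino acid (0.45), acute phase (-0.047) and cell division genes (-0.038), and muscle immediate early genes (0.0098). With the processed values they were liver hepatocyte markers (0.13), amino acid (0.65), acute phase (0.15) and cell division genes (0.10). Liver bile acid genes did so with quantile normalization within tissues (0.19), without background correction (0.16) and without the detection filter (0.16). Liver amino acid genes did so without background correction (0.11), with detection on both arrays (0.11) and with an offset of 50 (0.11). Muscle hepatocyte markers did so without the filter (0.35) and at a detection p-value under 0.05 (0.55), muscle unfolded protein response genes without the filter (0.15), and muscle immediate early genes with detection on both arrays (0.27). In liver, some hepatocyte markers and acute phase genes, such as Fgb and Hpx, lay near the brightest probes. They could shift less than other genes, so the low percentiles of these lists decide nothing.

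Among named genes under all settings, 110 comparisons with the main value lost 2-fold, 103 gained it and 0 changed sign past it, and 2806 stayed on the same side. No paired analysis was possible because each group holds 1 array.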

Other observations

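Globins and lymphocyte markers had lower values on the diabetes arrays of both tissues, and other blood cell markers were mixed. Macrophage markers had a median of 0.49 in liver and -0.018 in muscle. Neutrophil markers, with 2 measured in each tissue, had medians of -3.06 in liver and -0.039 in muscle. In liver these were Lcn2 at -4.75, also an acute phase gene, and S100a8 at -1.37. In muscle Lcn2 was at -0.078 and S100a8 was set to 0 by the rule for bounds, and neither was detected on both arrays. The neutrophil medians are thus no measure of blood cells alone. Hbb was at -0.87 in liver and -0.98 in muscle, and Hba-a1 at -0.66 and -1.14. Lymphocyte markers lay at percentiles 1.15 in liver and 0.18 in muscle, but in liver at 2.96 with median scaling and 3.13 with the authors' processed values, where they no longer stood apart. In muscle all 5 measured were bounds that could not lie above 0. The chemokine gene Ccl5, a product of T cells and others, was at -1.06 and -1.30 and was named after its values were seen. The other genes at least 2-fold apart in the same direction in both tissues, chosen likewise, were Csnk1d (1.25 in liver and 1.09 in muscle), Prkce (1.08 and 1.25) and Etfbkmt (-1.14 and -1.01).

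Naming the probes by the identifiers of the processed table, a check added after the data were seen, gave 133 genes at least 2-fold higher and 67 lower in liver, and 52 and 80 in muscle. Of these, 0 and 0 in liver and 0 and 1 in muscle were shared with the genes called under the identifiers of the non-normalized table. Independent lists would share 1.55, 0.34, 0.23 and 0.44. Gene names read from the processed table from row 252 on thus belong, by the match of values, to other probes than the values beside them.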
